A study of Xenopus laevis with 6 samples.

How the data were processed

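Gene expression was measured on 6 Affymetrix GeneChip Xenopus laevis Genome 2.0 arrays, which read transcript levels through sets of short oligonucleotide probes. The RNA came from animal caps, the ectodermal tissue cut from the top of the blastula, which forms epidermis when cultured alone and mesoderm or endoderm when exposed to activin. Per the labels' protocols, morpholinos (antisense oligonucleotides that block translation or splicing of a chosen transcript) were injected at the 4-cell stage, caps were cut at stage 9 and harvested at stage 15, and 250 ng of total RNA was amplified for each array. The control morpholino was given at 80 ng, ERK3 MO1 and MO2 were given together at 40 ng each (MO1/2), and ERK3 MO3 was given at 80 ng. ERK3 is an atypical MAP kinase encoded by mapk6.

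Per the labels, the authors normalized the scanned arrays with the robust multi-array average (RMA), which corrects background, forces the arrays to close signal distributions and summarises each probe set. The deposited values are intensity values on a linear scale, from 2.13 to 18347. The design fixed before the data were examined had taken them to be log2 values, so log2 was taken of every value first, with no constant added since 0 values lay at or below 0. All changes below are differences of these log2 values. RMA signals carry no detection call, and signals near the lower end of the scale compress the changes of weakly expressed genes.

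Of 32635 rows, 96 control probe sets were left out and 32539 probe sets were tested, with no filter on level. The platform annotation listed 1 gene symbol for 15495 probe sets, several for 279 and none for 16765. Of those with 1 symbol, 15384 matched a gene of the RefSeq gene table by identifier, 2 symbols were updated from it, and 11303 distinct symbols resulted. Symbols end in .L or .S for the long or short subgenome of this tetraploid frog, and the copies can share probes. No probe set carried the symbol mapk6, so the level of the ERK3 transcript was not analysed here.

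Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend). P-values were adjusted by Benjamini-Hochberg over all probe sets and called at 0.05. The effect of activin with retinoic acid (activin/RA) was tested with the morpholino as a block, and MO3 was set against MO1/2 in the same fit. The effect of the ERK3 morpholinos was tested in a second fit of culture, knockdown and their interaction. There the 2 reagents stood in for replicates, and the lone control array of each culture was assumed to vary like the others. Both fits left 2 residual degrees of freedom. In the first fit these hold the differences between the morpholinos in the effect of culture. The arrays come from 1 experiment with 1 array per group, so p-values measure only the spread between these arrays, which may be technical, and not the spread between clutches or experiments. The number of arrays limits the precision. Without a test, probe sets were also counted whose signal differed at least 2-fold from the control array of the same culture, in the same direction, with both reagents.

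On simulated arrays with 200 changed probe sets among 32539, a change of 2 on the log2 scale was recovered for 98.5% of probe sets in the activin/RA comparison, 86.0% in the untreated ERK3 comparison, 89.5% in the activin/RA ERK3 comparison, 34.5% in the difference between cultures and 96.0% between the reagents. A change of 1 was recovered for 45.0% in the activin/RA comparison and 35.5% in the mean ERK3 comparison, and for 0% in the other comparisons.

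Likewise 30 gene lists were fixed in advance, and each gene was represented by its probe set with the highest mean. Lists were tested with limma's camera at the preset correlation of 0.01 and again with a correlation estimated from the residuals, each adjusted over the 30 lists. Each list's median change was also placed among the medians of 10000 random lists matched on mean expression. With the estimated correlation 0 lists passed in any comparison, with smallest adjusted p of 0.318 for activin/RA and 0.390 for the mean ERK3 effect. 3 further lists (maternal transcripts, early gastrula genes and neurula genes) were written after the largest changes had been seen. The maternal list left out every symbol named among those changes, but not the other subgenome copy of such a gene. Camera p-values of these 3 lists were adjusted over the 3 alone. They carry a smaller correction than those of the 30 lists and cannot be set beside them.

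Named genes follow a rule fixed beforehand. For each comparison these are the 10 genes up and the 10 down with the largest change among passing probe sets that moved the same way in every single difference, reached above the median of all values on at least 1 array and carry 1 informative symbol. Knockdown comparisons with fewer were filled from genes changed 2-fold by both reagents, which are said not to pass. Up to 4 members of each gene list with the largest change are added. Where a gene has several probe sets these could disagree in sign, as for 3 of 32 such genes in the activin/RA comparison 6 of 31 in the untreated ERK3 comparison, 7 of 34 in the activin/RA ERK3 comparison, 5 of 28 in the mean ERK3 comparison, 5 of 26 in the difference between cultures and 10 of 28 between the reagents.

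The alternatives tried were the probe sets with a mean above the median, eBayes without the trend or with robust estimation, probe sets averaged per gene, cross-hybridising probe sets left out, median or quantile scaling of the arrays, a 2-fold minimum, other fits, each reagent alone and each array left out in turn.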

Results

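Transcript levels were measured in 6 pools of Xenopus laevis animal caps. Caps were cultured alone (untreated) or with activin and retinoic acid, a combination that turns animal cap cells towards mesoderm and pronephric fates. In each culture 1 array held caps with a control morpholino, 1 with ERK3 MO1/2 and 1 with ERK3 MO3. The series title places ERK3 in the formation of epithelial architecture, and the comparisons asked which transcripts depended on the culture, on the ERK3 morpholinos and on both. The median log2 signal lay between 5.08 and 5.14 on all arrays. Arrays of different culture correlated at r = 0.943 to 0.975 across probe sets, and the pair of ERK3 reagents correlated at r = 0.992 in untreated caps and 0.993 in activin/RA caps. The untreated control array correlated at r = 0.970 with untreated MO1/2 and 0.982 with untreated MO3, and at 0.970 to 0.975 with the activin/RA arrays. The activin/RA control array correlated at r = 0.988 and 0.989 with the ERK3 morpholino arrays of its culture. Probe sets are not independent replicates. The first principal component held 64.7% of the variance. It separated the cultures, and in both of them the ERK3 morpholino arrays lay on the untreated side of their control array.

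Activin/RA raised genes of mesoderm and endoderm formation. The largest increase among the named genes was that of xenf.L, whose log2 signal went from 2.09 to 2.22 in untreated caps to 9.70 to 9.94 in activin/RA caps (log2 change 7.66 ± 0.15 SE, limma adjusted p = 4.16e-06, higher in all 3 morpholino pairs). The forkhead gene of the axial mesoderm foxa4.S (6.32), asmtl.L (6.02) and the secreted antagonist gene cer1.S (5.66) rose, as did the ligand gene wnt8a.L (5.41) and pnhd.L (5.27). The homeobox gene lhx1.L, the paraxial protocadherin gene pcdh8.2.L (5.19), the homeobox gene cdx4.L (5.16) and foxa4.L (5.16) rose by close amounts. The named genes with the largest decreases were man1c1.S (-4.47), b4galnt1.L (-4.21), cplx1.L (-4.11), the endothelial receptor gene tek.S (-3.87), gpx4.L (-3.65), bves.S (-3.54), abhd12.S (-3.33), crmp1.L (-3.13), tmem115.S (-2.91) and cwc25.S (-2.87). These adjusted p-values were 0.000553 or smaller. The 4 probe sets of cwc25.S did not move together and ranged from -2.87 to 4.83, and those of tmem115.S ranged from -2.91 to -0.40. Among the increases, the weakest probe set stood at 0.38 for lhx1.L, 0.97 for cer1.S and 2.67 for xenf.L.

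Among the 30 gene lists fixed in advance, early and paraxial mesoderm genes had the largest median change. Of 39 genes 27 rose and 0 fell (28 rose and 2 fell adjusted over the list alone), with a median change of 2.07 (camera adjusted p = 1.47e-17, and adjusted p = 0.318 with an estimated correlation). Its leading members were wnt8a.L, lhx1.L, mix1.S (4.87) and the T-box gene eomes.S (4.47). Of 36 endoderm genes 24 rose and 2 fell (25 and 3 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 8.43e-15, and 0.318 as the adjusted p with an estimated correlation), led by cer1.S, mixer.L (5.04) and the copies of mix1. Of 20 notochord genes 9 rose, with foxa4.S and the brachyury gene tbxt.S (4.07) in front (9 adjusted over the list alone, camera adjusted p = 0.000142, adjusted p = 0.318 with an estimated correlation). In the list of intermediate mesoderm and pronephros 9 of 30 genes rose (9 adjusted over the list alone, camera adjusted p = 0.000694, adjusted p = 0.322 with an estimated correlation). These were led by the regulators lhx1.L, foxc2.L (3.63), osr1.L (2.98) and foxc1.L (2.32), while the kidney regulator pax8.L stayed between 2.49 and 3.11 on all 6 arrays. The median of this list was 0.06 in the control morpholino pair, 0.23 in the MO1/2 pair and 0.23 in the MO3 pair. That of the notochord list was 0.24, 0.50 and 0.72 in these pairs. The retinoic acid response list had 14 of 38 genes higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 1.97e-06, adjusted p = 0.318 with an estimated correlation). Its largest changes were in the retinoid-metabolising enzymes dhrs3.L (4.27), cyp26a1.S (3.08) and cyp26a1.L (2.95) and in cdx1.S (3.14).

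The Wnt and FGF target lists also passed upwards with activin/RA in the mean of the 3 morpholino pairs, as did the BMP list without a rise of its median in the control pair, while the Notch target list did not pass (4 of 21 rose and 4 fell, 6 and 5 adjusted over the list alone, camera adjusted p = 0.625). In the Wnt list 11 of 23 genes rose (12 adjusted over the list alone), led by cdx1.S, dkk1.S (2.56), cdx2.L (2.55) and sp5.L (1.87) (camera adjusted p = 1.97e-06, adjusted p = 0.387 with an estimated correlation). In the list of FGF and ERK1/2 targets 11 of 27 rose and 1 fell (13 and 3 adjusted over the list alone), with cdx4.L, the ligand gene fgf8.L and the phosphatase gene dusp5.S (1.46) in front (camera adjusted p = 0.00013, adjusted p = 0.318 with an estimated correlation). The 4 probe sets of fgf8.L ranged from 0.19 to 2.56. In the BMP list 10 of 33 rose and 2 fell (13 and 2 adjusted over the list alone), with ventx1.2.S (2.15), msx2.L (2.08) and ventx1.1.S (2.02) in front (camera adjusted p = 0.00013, adjusted p = 0.681 with an estimated correlation). The BMP median was -0.12 in the control morpholino pair, 0.80 in the MO1/2 pair and 0.75 in the MO3 pair, and ventx1.1.S differed by 0.63, 3.40 and 2.04 in these pairs. Among epidermal lists, the transcription factors passed upwards in the mean of the pairs, with medians of 0.02 in the control pair, 0.73 in the MO1/2 pair and 0.46 in the MO3 pair, and with 8 of 31 higher and 2 lower (10 and 3 adjusted over the list alone, median 0.39, camera adjusted p = 0.0155, adjusted p = 0.698 with an estimated correlation). In the desmosome and hemidesmosome list 5 of 13 rose (5 adjusted over the list alone), led by dst.L (1.68) and pkp3.L (1.52) (camera adjusted p = 0.0158, adjusted p = 0.698 with an estimated correlation), and the control pair had a median of -0.09. The keratins krt12.4.L (4.47) and krt12.4.S (3.70) rose, and the keratin list did not pass (5 of 22 rose and 2 fell, 6 and 3 adjusted over the list alone, camera adjusted p = 0.248). Of 59 proliferation genes 16 fell and 2 rose (23 and 3 adjusted over the list alone), with the phosphatase gene cdc25a.S (-2.59) and the spindle checkpoint gene mad2l1.L (-1.92) in front (camera adjusted p = 0.00265, adjusted p = 0.387 with an estimated correlation). The 3 probe sets of cdc25a.S ranged from -2.59 to -0.38. Of 53 muscle genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.742), and the myogenic regulator myod1.L fell by 1.34. On each array 4 or 5 of the 53 muscle genes lay above the median of all values.

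In all, 6668 of 32539 probe sets passed for activin/RA (3123 higher and 3545 lower), and 1911 of these changed at least 2-fold. The number depended on the arrays used. It was 10628 without the untreated control array, 10636 without the activin/RA control array, 1859 and 1933 without the untreated or activin/RA MO1/2 array, 2559 and 2576 without the untreated or activin/RA MO3 array, and 2860 without the morpholino block.

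**Figure D1:**
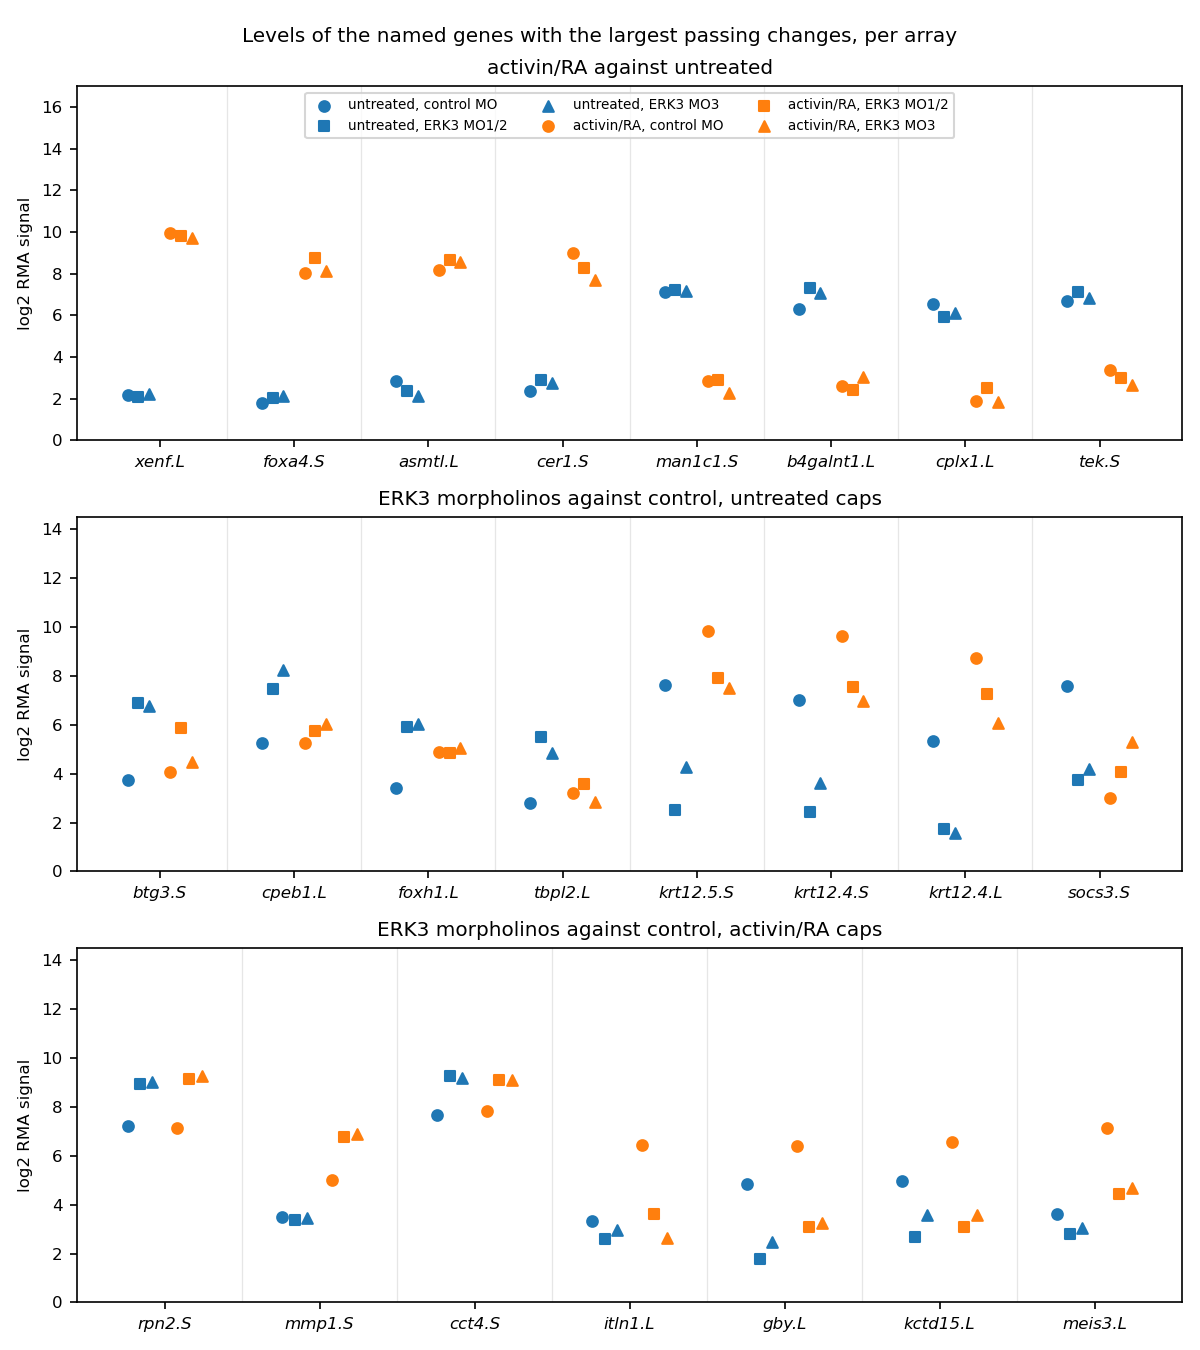
Log2 RMA signal of the named genes with the largest passing changes up and down in the 3 comparisons given as panel titles, each point 1 array (blue untreated, orange activin/RA, circle control morpholino, square MO1/2, triangle MO3). In the top panel xenf.L lies at 2.09 to 2.22 in untreated caps and 9.70 to 9.94 in activin/RA caps, and in the middle panel krt12.5.S lies at 7.64 in the untreated control and at 2.53 and 4.26 with the ERK3 morpholinos.

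In untreated caps the ERK3 morpholinos lowered epidermal genes. The largest decrease among the named genes was that of the keratin gene krt12.5.S, from 7.64 in the control to 2.53 with MO1/2 and 4.26 with MO3 (log2 change -4.25 ± 0.60 SE, limma adjusted p = 0.0178). The keratins krt12.4.S (-3.97), krt12.4.L (-3.69) and krt70.L (-3.39) fell with it. Also lower were the cytokine signalling inhibitors socs3.S (-3.61) and socs3.L (-3.21), the homeobox gene dlx3.S (-3.56), capn8.1.L (-3.22), the ligand gene kitlg.L (-3.18) and tbc1d24.2.L (-3.17). The named genes with the largest increases were btg3.S (3.08), the translational regulator cpeb1.L (2.61), the activin-signalling partner foxh1.L (2.56), the oocyte TBP paralogue tbpl2.L (2.38), tmem106b.S (2.31), ssx2ip.S (2.23), mylip.S (2.23), the Nodal co-receptor gene tdgf1.1.L (2.18), rnf112.1.S (2.17) and tbp.L (2.15). The adjusted p-values of these genes lay between 0.0138 and 0.0475, and MO1/2 and MO3 moved each in the same direction. Stored egg transcripts moved with this comparison. Of 46 maternal transcripts on a list written after the largest changes were seen, 8 rose and 0 fell (11 and 2 adjusted over the list alone). Adjusted over only the 3 lists written then, camera gave p = 0.000626, and p = 0.140 with an estimated correlation.

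The lists with the lowest medians were those of epidermal transcription factors and of BMP targets, which share several genes. Of 31 epidermal transcription factors 18 fell and 0 rose (22 fell and 1 rose adjusted over the list alone), with a median of -1.30 (camera adjusted p = 1.3e-13, adjusted p = 0.451 with an estimated correlation). Examples were dlx3.S, gata3.S (-3.13), ventx1.1.S (-2.93) and dlx3.L (-2.73). The 3 probe sets of dlx3.L ranged from -2.73 to -0.83. Of 33 BMP targets 18 fell and 0 rose (26 fell adjusted over the list alone), with a median of -1.18 and ventx3.2.S (-2.87) among its leading members (camera adjusted p = 3.17e-17, adjusted p = 0.446 with an estimated correlation). Of 22 epidermal keratins and structural genes 6 fell (10 adjusted over the list alone), including krt7.L (-2.68), with a list median of -0.18 (camera adjusted p = 0.000621, adjusted p = 0.425 with an estimated correlation). The 5 probe sets of krt7.L ranged from -2.83 to -0.21. Genes of particular epidermal cell types fell as well. In the ionocyte list 6 of 20 fell (7 adjusted over the list alone), led by the proton pump subunits atp6v1g3.L (-2.34) and atp6v0a4.L (-1.92) and the ionocyte regulator foxi1.L (-1.97) (camera adjusted p = 0.000621, adjusted p = 0.425 with an estimated correlation). In the mucus and secretory cell list 4 of 11 fell and 1 rose (7 and 1 adjusted over the list alone), with otogl2.L (-2.28) and agr2.L (-1.49) lower and the amine transporter gene slc18a2.L (1.49) higher (camera adjusted p = 0.00262, adjusted p = 0.425 with an estimated correlation). Of 30 multiciliated cell genes 2 fell (2 adjusted over the list alone), the list did not pass (camera adjusted p = 0.0571), and the value for the ciliogenesis regulator foxj1.S was -2.95 (adjusted p = 0.106). In the cement and hatching gland list 2 of 11 fell (6 adjusted over the list alone), ag1.L (-1.56) and agr2.L (camera adjusted p = 0.00262, adjusted p = 0.425 with an estimated correlation). Of the 30 lists 12 passed, all with lower expression.

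Lists of cell junctions and polarity were each tested against all other genes, not against each other. Of 24 adherens junction genes 2 fell (4 adjusted over the list alone), the E-cadherin gene cdh1.S (-2.61) and zyx.S (-1.14), with a list median of -0.27 (camera adjusted p = 0.000621, adjusted p = 0.482 with an estimated correlation). Of 13 desmosome and hemidesmosome genes 3 fell and 1 rose (4 and 1 adjusted over the list alone). The cornified envelope genes evpl.L (-2.45) and ppl.L (-1.48) were lower and the desmosomal cadherin gene dsc3.S (1.03) was higher (camera adjusted p = 0.00262, adjusted p = 0.482 with an estimated correlation). The 4 probe sets of ppl.L ranged from -1.91 to -0.17. Of 27 tight junction genes 2 rose and 1 fell (3 and 3 adjusted over the list alone), with cldn12.L and cldn6.2.S (0.68) higher, and the list did not pass (camera adjusted p = 0.787). Of 21 apicobasal polarity genes 0 passed (0 adjusted over the list alone, camera adjusted p = 0.591). Of the 6 measured genes in the list of ERK3 and its partners 0 passed (0 adjusted over the list alone, camera adjusted p = 0.816). In the p53 response list 2 of 25 genes rose, mdm4.S (1.18) and ei24.S, and the list did not pass (2 adjusted over the list alone, camera adjusted p = 0.614).

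In all, 2180 probe sets passed in untreated caps (1021 higher and 1159 lower) and 1619 of them changed at least 2-fold. Without the untreated MO1/2 array 322 passed. Without a test, 1492 probe sets changed at least 2-fold with both reagents, 667 higher and 825 lower. MO1/2 alone changed 3022 and MO3 alone 1783. Across probe sets the changes with MO1/2 and MO3 correlated at r = 0.86 with a covariance of 0.251. Both were measured against the same control array, and simulated unchanged groups sharing 1 control gave r = 0.50 and a covariance of 0.0362. The simulated spread left out differences between the injected groups, so it cannot tell an ERK3 effect from an unusual control group.

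**Figure D2:**
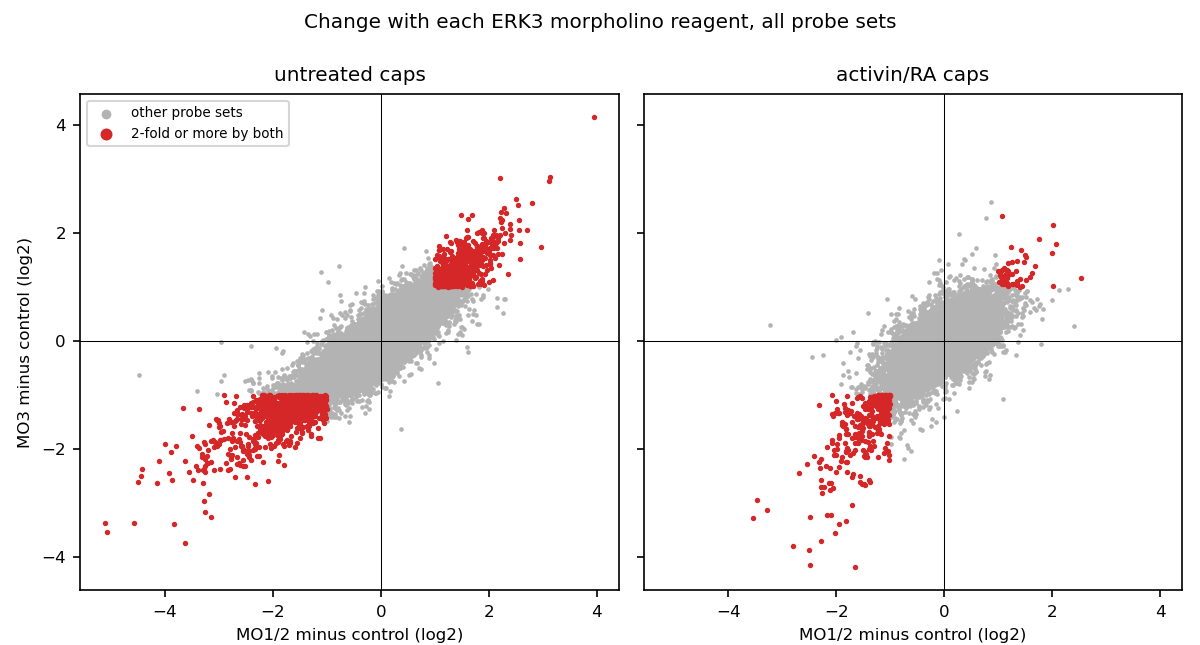
Log2 change against the control array with MO1/2 (horizontal axis) and with MO3 (vertical axis) in untreated and in activin/RA caps, each point 1 probe set, in red where both reagents changed it at least 2-fold in the same direction. There are 1492 red points in untreated caps and 345 in activin/RA caps, and points of a panel share 1 control array.

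In activin/RA caps the ERK3 morpholinos lowered, most among the named genes, the secreted lectin gene itln1.L, from 6.42 to 3.62 with MO1/2 and 2.62 with MO3 (log2 change -3.30 ± 0.39 SE, limma adjusted p = 0.0421). gby.L (-3.21), kctd15.L (-3.21), the Hox cofactor meis3.L (-2.56), fut6.S (-2.47), s100a10.S (-2.28), the synaptic vesicle gene syt1.L (-2.26), a probe set of krt7.L (-2.07), gdpd1.L (-1.95) and tmem72.L (-1.75) also fell, while a second probe set of fut6.S stood at 0.08. The named genes that rose were rpn2.S (2.07), the collagenase gene mmp1.S (1.83) and the chaperonin subunit gene cct4.S (1.25). rpn2.S was also higher in untreated caps, at 7.21 in the control against 8.94 and 9.02. Genes changed 2-fold by both reagents without passing included pabpn1l.S (1.46), jun.L (1.41), btg4.L (1.44) and myod1.L (1.31) on the higher side.

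In activin/RA caps 11 of the 30 lists passed with the preset correlation, and with an estimated correlation the adjusted p was 0.552 for each of them. The medians were -0.52 for epidermal transcription factors (0 of 31 passed, 6 fell adjusted over the list alone, camera adjusted p = 1.24e-07) and -0.34 for BMP targets (0 of 33, 3 fell adjusted over the list alone, camera adjusted p = 1.17e-05). They were -0.24 for epidermal keratins and structural genes (0 of 22, 6 fell adjusted over the list alone, camera adjusted p = 1.3e-05) and -0.36 for Wnt targets (0 of 23, 4 fell adjusted over the list alone, camera adjusted p = 0.000439). In the retinoic acid list, with a median of -0.33, meis3.L fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000188), and the value for hoxb4.S was -2.04 without passing. Early and paraxial mesoderm genes had a median of -0.04, above that of 26.01% of random lists (0 of 39 passed, 7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0041), with mespa.L at -1.81 and msgn1.L at -1.33, neither passing. The list of FGF and ERK1/2 targets was the only one of the 30 that passed upwards, with a median of 0.19 (0 of 27 passed, 7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0145). Its early response genes jun.L and fos.S (1.23) did not pass. The mucus and secretory cell list had a median near 0, above that of 51.12% of random lists, and a mean of -0.75, and passed downwards (1 of 11 fell, 4 adjusted over the list alone, camera adjusted p = 0.0109), with itln1.L in front. Maternal transcripts, on the list written after the largest changes were seen, had a median of 0.18 (0 of 46 passed, 0 adjusted over the list alone). Adjusted over only the 3 lists written then, camera gave p = 0.00031, and p = 0.129 with an estimated correlation.

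In all, 45 probe sets passed in activin/RA caps, 4 higher and 41 lower. With limma 0 passed among the probe sets with a mean above the median (1886 at an unadjusted p under 0.05) and 0 without the activin/RA MO3 array (2977 at an unadjusted p under 0.05). The number was 27 without the activin/RA MO1/2 array, 4 without either the untreated MO1/2 or the untreated MO3 array, and 16 without the intensity trend. Without a test, 345 probe sets changed at least 2-fold with both reagents, 51 higher and 294 lower, with 783 for MO1/2 alone and 599 for MO3 alone. The changes with the reagents correlated at r = 0.71 with a covariance of 0.100, again with a shared control array. Of the 45, 41 had the same sign in untreated caps.

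Averaged over both cultures, the ERK3 morpholinos lowered the same keratins, krt12.5.S (-3.19 ± 0.42 SE, limma adjusted p = 0.0146), krt12.4.S (-3.17), krt70.L (-3.09), krt12.4.L (-2.88) and krt7.L (-2.67). The 5 probe sets of krt7.L ranged from -2.67 to -0.38. gby.L (-2.98), the otogelin-like gene otogl2.L (-2.73), dlx3.S (-2.63), kitlg.L (-2.58) and gnb3.L (-2.53) were lower too. Raised were btg3.S (2.09), rpn2.S (1.92), tmem106b.S (1.72), the oocyte poly(A)-binding gene pabpn1l.S (1.69), btg4.L (1.67), mylip.S (1.63), cpeb1.L (1.62), tbp.L (1.55), zfp36l2.1.S (1.49) and tpcn2.L (1.48). BTG4 removes maternal transcripts in vertebrate eggs and embryos. The lists of epidermal transcription factors (18 of 31 fell, 23 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.52e-14) and BMP targets (17 of 33 fell, 23 adjusted over the list alone, camera adjusted p = 3.56e-15) had adjusted p = 0.390 with an estimated correlation. Of the 30 lists 15 passed, all with lower expression. Of the 46 maternal transcripts 7 rose and 0 fell (11 adjusted over the list alone). Adjusted over only the 3 lists written after the largest changes were seen, camera gave p = 7.39e-05, and p = 0.110 with an estimated correlation. In all, 2562 probe sets passed (1128 higher and 1434 lower), against 1005 in an additive fit, where 912 passed for MO1/2 alone and 0 for MO3 alone (limma, 5211 at an unadjusted p under 0.05). The number was 1360 without the untreated MO1/2 array, 646 without the activin/RA MO1/2 array and 1541 without the activin/RA MO3 array.

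Probe sets changed 2-fold by both reagents overlapped between the cultures, with 15 higher in both (1.05 for independent lists), 123 lower in both (7.45 for independent lists) and 4 in opposite directions (7.32 for independent lists). The cultures share no arrays in these comparisons, but each morpholino was cultured both ways in 1 experiment. A difference between the injected groups that is not due to ERK3 could therefore recur in both cultures. Of the 2180 probe sets that passed in untreated caps, 88.9% had the same sign in activin/RA caps, and the median ratio of the activin/RA to the untreated change was 0.33. Choosing them by their untreated change can lower this ratio even where the effects are equal. Across cultures, with no array in common, changes correlated at r = 0.56 for MO1/2 and 0.41 for MO3.

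Whether the ERK3 morpholino effect differed between the cultures was tested by the interaction. No single probe set passed (limma, smallest adjusted p = 0.0533), while 3061 had an unadjusted p under 0.05 against 1627 by chance. Leaving out the activin/RA MO1/2 array gave 2 passing probe sets, leaving out either untreated ERK3 morpholino array 1, robust estimation 2 and median scaling 1. The simulations recovered a difference of 2 on the log2 scale for 34.5% of probe sets only. Among lists, BMP targets differed most, with a median change of -1.18 in untreated and -0.34 in activin/RA caps (0 of 33 genes passed, 8 higher adjusted over the list alone, camera adjusted p = 8.98e-12). Epidermal transcription factors differed in the same direction, at -1.30 and -0.52 (0 of 31 genes passed, 8 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.04e-07). Both had adjusted p = 0.731 with an estimated correlation. socs3.S had the largest difference of the named list members, with a change of -3.61 in untreated caps and 1.70 in activin/RA caps (adjusted p = 0.196 for the difference).

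MO3 was set against MO1/2 over both cultures to find where the reagents differed. No probe set passed (limma, smallest adjusted p = 0.108), and 1973 had an unadjusted p under 0.05 against 1627 by chance. The spread of this fit also holds the difference between cultures in the ERK3 morpholino effect. It can therefore hide differences between the reagents. When either control array was left out, 742 (untreated control) or 778 (activin/RA control) passed. The ciliogenesis gene foxj1.S was 2.03 higher with MO3 (adjusted p = 0.431), and snai2.L 1.28 higher (adjusted p = 0.416), neither passing. The lists of epidermal transcription factors (median 0.32, camera adjusted p = 0.000129) and BMP targets (median 0.32, camera adjusted p = 0.000307) were higher with MO3, each with 0 genes passing, 0 adjusted over the list alone and adjusted p = 0.817 with an estimated correlation. Both reagents had these lists below the control.

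**Figure D3:**
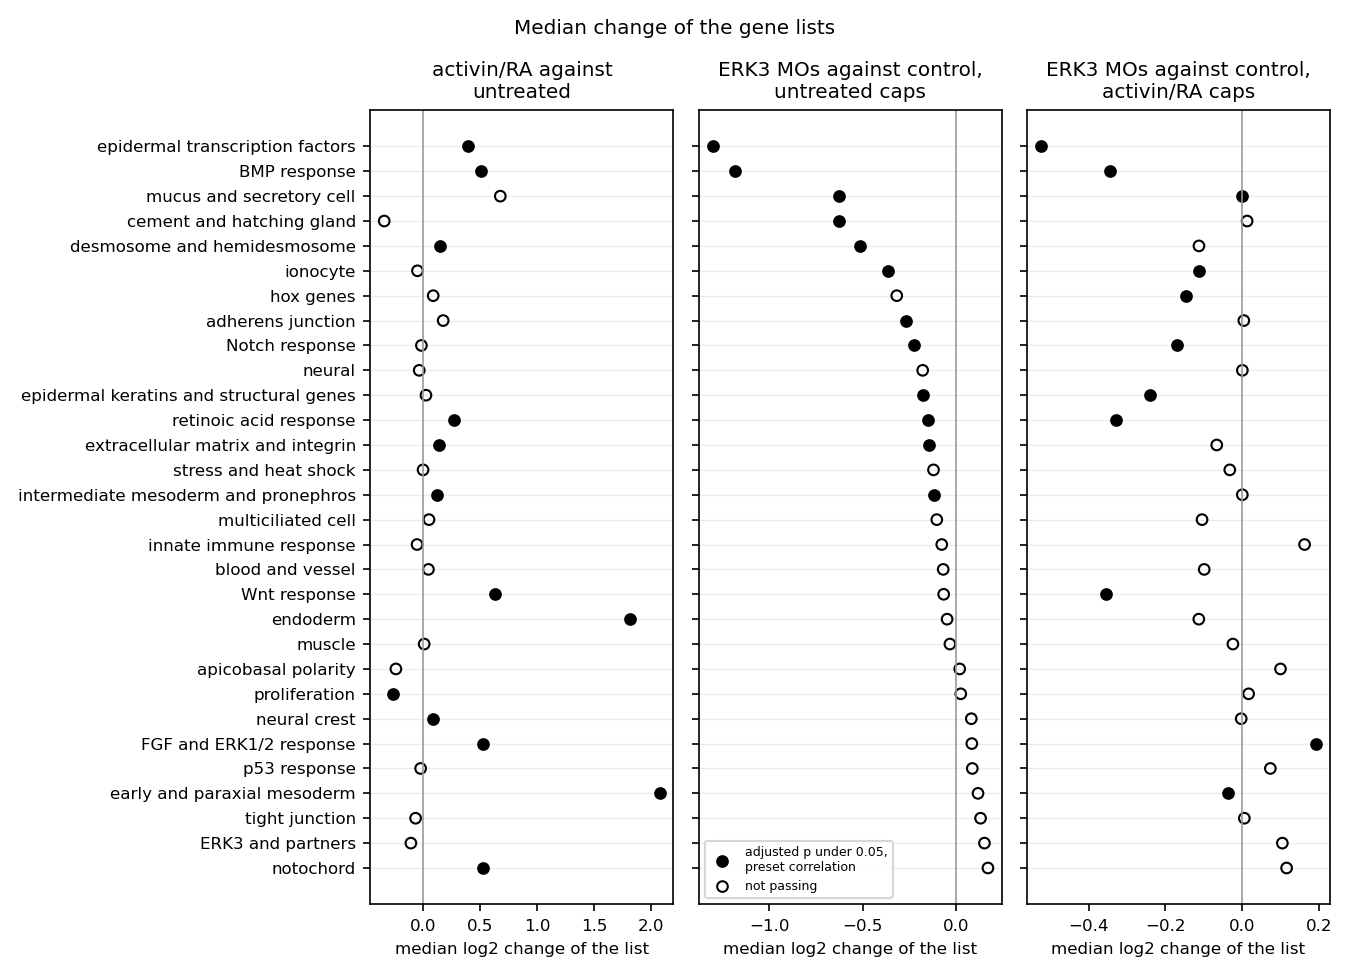
Median log2 change (horizontal axis, scaled separately in each panel) of the 30 gene lists in the activin/RA comparison and in the ERK3 morpholino comparisons of each culture, filled where camera with the preset correlation passed. Epidermal transcription factors and BMP targets have the lowest medians in untreated caps, at -1.30 and -1.18, and early and paraxial mesoderm the highest with activin/RA, at 2.07, and with an estimated correlation 0 lists passed.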

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

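The tests with maternal transcripts use a list written after the largest changes had been seen, and the bounds of the tests were written before their values were computed. Added afterwards were the rule that a median inside the central 95% of random lists decides nothing, and the tests of age on early gastrula genes and of parentage on gene lists. The reading of age on the mesoderm and endoderm lists was also added afterwards. The ERK3 morpholino effect differed between the cultures for 9 gene lists by the interaction test with the preset correlation, and for 0 with an estimated correlation (limma camera, smallest adjusted p = 0.731). In each case the value is the median difference, activin/RA minus untreated caps. It was 0.95 for BMP targets, 0.86 for epidermal transcription factors, 0.31 for innate immune genes, 0.30 for adherens junction, 0.27 for desmosome and hemidesmosome, 0.24 for cement and hatching gland, 0.21 for ionocytes, 0.20 for stress and heat shock genes and -0.37 for early and paraxial mesoderm. The reagents differed, in the median of MO3 minus MO1/2, for epidermal transcription factors (0.32), BMP targets (0.32) and Notch targets (0.18, camera adjusted p = 0.0232) with the preset correlation. With an estimated correlation each of these 3 had adjusted p = 0.817.

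Lower epidermal genes and higher other genes in untreated ERK3 morpholino caps were weighed against age and against p53 and innate immune responses to the ERK3 morpholinos. The control caps were injected with a morpholino too, so a response common to all injected caps would cancel and was not weighed. The median of 46 maternal transcripts, 0.28 on the log2 scale, lay above 99.99% of random lists, as caps younger at harvest would show (camera adjusted p = 0.140 with an estimated correlation). In activin/RA caps, where 0 of 46 passed, their median lay above 99.95%. In untreated caps the median of 22 neurula genes (-0.13, 0 passed) lay above 1.92% of random lists. That of 29 early gastrula genes (0.12, 3 rose and 0 fell) lay above 79.16%. These 2 lists were also written after the largest changes had been seen, and few neurula genes lay above the median of all values. The maternal list was written after the largest changes had been seen and did not leave out other subgenome copies of those genes. Its rise is therefore no independent support for age. That the ERK3 morpholino caps were behind their controls in development stays open as a candidate explanation. Whether this came through timing, injection or loss of ERK3 was not tested. The median of p53 targets lay above 61.92% of random lists and that of innate immune genes above 7.52%, both inside the central 95% of random lists, and the innate immune value met the bound written against that response (at or below 50%), but it is left open since random lists reach it too and the median in activin/RA caps lay above 99.69%. The loss of ERK3 itself stays open as the biological explanation.

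The probe sets that passed for activin/RA were weighed against chance, age and parentage. Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many passing probe sets, the real one with 6668, and the highest other gave 0. This decides nothing, since every other split mixes the cultures and leaves their difference in the spread. Besides, 10 splits are too few for a share under 0.05. For age, maternal transcripts lay above 3.96% of random lists, between the bounds set for older caps and against them. The early gastrula list (median above 100% of random lists) holds genes already seen among the largest changes and so decides nothing. Caps cultured alone form epidermis, so age alone would not raise mesoderm and endoderm genes. Yet 27 of 39 genes on the early and paraxial mesoderm list fixed in advance rose and 0 fell, and 24 of 36 on the endoderm list rose and 2 fell. This argues against age as the cause of these rises, and for other genes age stays open. Sequence differences between the parents would not pick genes by what they do. Yet of the lists fixed in advance those of early and paraxial mesoderm (27 of 39 rose), endoderm (24 of 36), retinoic acid response (14 of 38) and Wnt targets (11 of 23) each had a median above 100% of random lists. This argues against sequence differences as the cause of these rises, but not as a test set beforehand. The 4 lists were picked after their values had been seen, and BMP targets, epidermal transcription factors and mucus and secretory cell genes also lay above 100%. With an estimated correlation the camera adjusted p of the 4 lists was 0.318 to 0.387. For genes outside the 4 lists sequence differences stay open. A second probe set disagreed for 47.7% of 172 passing 2-fold probe sets against 44.3% of 61 for the ERK3 morpholinos (Fisher's exact test, two-sided, p = 0.658). This decides nothing, since no label names the parents and the ERK3 morpholino comparison could carry such differences too. Parentage was not weighed for the ERK3 morpholino effect. Activin/RA remains the explanation that the design names for the activin/RA comparison.

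Larger changes with MO1/2 than with MO3 in untreated caps (3022 against 1783 probe sets changed 2-fold) could come from a single effect at 2 strengths. Among the 45 probe sets that passed in activin/RA caps, 51.1% had a MO3 to MO1/2 ratio under 0.9 in untreated caps, with a median ratio of 0.892. This decides nothing, since the test that chose them takes its error partly from the gap between MO1/2 and MO3 in untreated caps and so favours ratios near 1. No biological explanation was tested.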

How the results depend on the processing

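The counts of gene lists with a single reagent were chosen after the results were seen, and the other alternatives in this part were planned. With the probe sets whose mean lies above the median, without the intensity trend, with robust estimation, without cross-hybridising probe sets and with median or quantile scaling, between 5033 and 6778 probe sets passed for activin/RA, 1902 to 2807 for the mean ERK3 morpholino effect and 1652 to 2393 for untreated caps. For activin/RA caps the count was 0 above the median, 16 without the trend, and 39 to 57 in the others. The difference between the cultures gave 2 with robust estimation, 1 with median scaling and 0 in the others, and MO3 against MO1/2 gave 0 in all of these.

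Averaged per gene, with fewer units tested, 2943 genes passed for activin/RA, 937 for the mean ERK3 effect, 771 in untreated caps, 3 in activin/RA caps and 2 between the reagents. The averages turned cwc25.S to 0.71 and lsr.S to -1.05 for activin/RA, genes with 4 probe sets each that moved apart. A 2-fold minimum left 1911 for activin/RA and 729 for the mean effect. The directions of the mean effect shifted too, with 209 higher and 520 lower at the 2-fold minimum. They were 954 higher and 1614 lower with median scaling, and 486 higher and 451 lower averaged per gene. Without the morpholino block 2860 passed for activin/RA, and the additive fit gave 1005 for the mean effect, 912 for MO1/2 alone and 0 for MO3 alone. The cause was not tested for these fits.

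Leaving out single arrays gave 1859 (without untreated MO1/2) to 10636 (without the activin/RA control) for activin/RA. There the partner of a left-out array adds nothing, so each count rests on the other morpholino pairs. Without a control array the spread comes only from the gap between the MO1/2 and MO3 pairs, and no longer holds the gap between the control and ERK3 morpholino pairs. In the ERK3 morpholino comparisons lone arrays were assumed to vary like the other groups. The mean effect ranged from 646 to 3048, untreated caps from 322 to 2482, activin/RA caps from 0 to 45, the difference from 0 to 2 and the reagents from 0 to 778. Comparisons that need a lone control array could not be fitted without it. The cause of these shifts was not tested.

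The count changed 2-fold by both reagents in untreated caps was 948 above the median level, 4440 at 1.5-fold, 275 at 3-fold, 3022 with MO1/2 alone and 530 averaged per gene. In activin/RA caps these were 136, 1482, 74, 783 and 121, and 599 with MO3 alone. Each threshold moves its count by construction. With an estimated correlation 0 gene lists passed in each of the 6 comparisons, while genes as means of their probe sets gave 12 for activin/RA, 17 for the mean effect and 13 in untreated caps. With 1 reagent 15 lists (MO1/2) and 12 lists (MO3) passed for the mean effect.

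Of the values of named genes under these alternatives for activin/RA, 1745 kept the call, 159 lost it, 28 gained it and 2 reversed. A change of direction was counted as reversed only where either fit passed. Values that passed in neither fit count as kept whatever their direction. For the mean ERK3 effect 1522 kept the call, 249 lost it and 59 gained it, in untreated caps 1373, 135 and 34, and in activin/RA caps 1452, 64 and 3. For the difference between cultures 1265 kept the call and 2 gained it, and between the reagents 1408 and 98. Array signals near background compress changes, so weakly expressed genes are seen less well.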

Other observations

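The comparisons in this part were chosen after the results of the comparisons above were seen. Single cell cycle genes rose or fell under the ERK3 morpholinos in untreated caps, while 49 of 59 proliferation genes did not pass. The embryonic cyclins ccna1.S (1.97), ccna1.L (1.84) and ccnb1.S (1.64) rose, while ccnd1.S (-1.29), ccnb3.L (-1.17) and top2a.L (-1.52) fell, and the list of 59 proliferation genes had a median of 0.02 (6 rose and 4 fell, 11 and 8 adjusted over the list alone, limma camera adjusted p = 1). The endoderm list did not pass in untreated caps (2 of 36 rose and 5 fell, 3 and 7 adjusted over the list alone, camera adjusted p = 0.144). Of its members gata4.L (-2.90) and gata6.S (-1.52) fell on 1 probe set each, while their second probe sets stood at -0.05 and 0.19. The neural crest list had 4 genes higher, among them ets1.S (1.83) and twist1.L (1.40), and 6 lower, among them pax3.L (-1.84) and tfap2a.S (-1.73) (6 and 9 adjusted over the list alone, median 0.08, mean -0.01, camera adjusted p = 0.446). The 5 probe sets of pax3.L ranged from -1.84 to -0.06. ccnb3.L and top2a.L were chosen after their values were seen.

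Signals of different probe sets are not on a common scale, so the levels that follow do not tell which genes were expressed. Levels of 1 probe set can be compared between arrays, but the stage that the caps had reached was not tested. Of 22 neurula genes on a list written for this purpose, 1 or 2 lay above the median of all values on each array. The cardiac actin gene actc1.L, a muscle marker, lay between 1.86 and 2.48, the hindbrain gene egr2.L between 2.06 and 2.63, and the kidney regulator pax8.L between 2.49 and 3.11, while tubb2b.S lay between 6.23 and 8.09 and cdx1.S between 7.59 and 8.60 in activin/RA caps. Of 29 early gastrula genes, 20 to 22 lay above the median in activin/RA caps, among them mixer.L at 8.13 to 8.52 and eomes.S at 6.45 to 7.21, and 2 or 3 in untreated caps. Between the cultures 24 of these 29 genes rose with activin/RA and 0 fell, while 1 of the 22 neurula genes rose and 0 fell. Of 46 maternal transcripts 39 to 41 lay above the median on each array.

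On the first principal component the ERK3 morpholino arrays lay below their control in both cultures, at -76.9 and -60.2 against -14.6 in untreated caps and at 41.0 and 43.3 against 67.3 in activin/RA caps.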
